A study of Mus musculus with 24 samples.

How the data were processed

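RNA sequencing libraries were made from brain hemispheres of male C57BL/6 mice, an inbred laboratory strain, with the poly(A)-selecting TruSeq version 2 kit, which does not mark the strand of a transcript. Samples were grouped by age and housing as the sample labels give them: 7 control and 5 enriched mice at 5 months, and 6 control and 6 enriched mice at 24 months. Enriched housing in general means a cage with added objects, shelter or exercise that raise sensory, motor and social activity. The cage contents and the length of the stay were not given in the sources used here, nor was any batch, litter or pairing of animals, and the replicate numbers only name the libraries. The labels number the samples of each group in 1 block, so anything done in the order of these numbers cannot be separated from the groups.

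Per the submitters' processing notes, bcl2fastq 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4 were used with the mouse build GRCm38, the usual tools for base calling, alignment and counting of reads per gene. The annotation release and the settings for strand and for reads that map to several places were not given in the sources used here. The authors deposited whole read counts per Ensembl gene for all 24 libraries, and these counts were the measurement tested. Overlapping and antisense genes, and near-identical copies such as C4a and C4b, histone genes, the clustered protocadherins, H2 genes, Hspa1a and Hspa1b, and ribosomal protein genes with many pseudogenes, may share or lose reads in such counts, so single members of these families are uncertain. The authors also deposited a table named RPKM. Its values were set against the counts over 5275 genes. The ratios of the divisors between columns repeated after 44 genes down the table (largest SD of the log ratio 4.76e-05, against 0.644 at a period of 24). Across the table the divisors repeated every 4 columns. Scaling by gene length cancels in ratios between columns and was not tested. Divisors for 1 gene differed between columns by ratios from 0.263 to 3.80, and column sums followed the total counts with a Spearman correlation of 0.989. The deposited RPKM values are thus not scaled to the depth of their own library and served only as an alternative that had been fixed beforehand.

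The count table held 47729 genes. Symbols came from a table of gene names for 47224 of them and from the GENCODE M21 annotation of GRCm38 for 86 more, while 419 had neither; coordinates are from that annotation, counted from 1. Total counts per library ran from 16.4 M to 74.4 M with a median of 25.2 M. Within groups the most similar pair of libraries had a chi-square of 2.09 per degree of freedom over genes with at least 20 counts, above the value of 1 that resequencing of 1 library would give, so every library was counted as a separate animal. The labels number the samples apart from each other but do not state that each came from its own mouse, which every p-value here assumes.

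The test was edgeR 4.0.16 (R 4.3.3): TMM scaling, the filterByExpr filter on the 4 groups, which left 17410 genes, and the quasi-likelihood F test in 1 fit of all 24 libraries with 4 group means. Contrasts were enriched minus control at 5 months, at 24 months and averaged over both ages, 24 minus 5 months in controls and in enriched mice, and the interaction, which is the enrichment effect at 24 months minus that at 5 months. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2 scale with their SE, and CPM means per group are on TMM-scaled library sizes with the SD over libraries. Per comparison 870.5 of the genes tested would have an unadjusted p under 0.05 by chance.

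Of 52 lists of cell type, region and pathway genes written before the data were examined, 49 had at least 5 tested members. Each was tested with limma 3.58.1's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with the correlation estimated per list. Members are counted over all genes tested and, separately, adjusted over the list alone. Mean log2 CPM per list and library (with a prior count of 2) was compared between groups by exact two-sided permutation tests. The named genes followed a rule fixed beforehand. Per comparison these were the 10 higher and the 10 lower called genes with the smallest p, a mean log2 CPM of at least 1 and a symbol that is not a provisional name. Where none passed, the 5 genes with the smallest p were taken. Up to 4 members of each described list with the smallest p, and Gfap, C4b, Bdnf, Fos, Arc, Ttr, Mbp and Dcx, were added throughout.

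Before use, the fits were tested on simulated counts with 200 changed genes drawn at the means and depths of these libraries. At a 1.5-fold change 76% of the changed genes were recovered for enrichment at 5 months, 74% at 24 months, 84% for age in controls, 78% for age in enriched mice and 66% for the interaction; at a 1.25-fold change these shares were 56%, 46%, 56%, 60% and 26%. The immediate early gene list, lowered in 5 simulations, was called in each of them, with 0 other lists called. The simulated genes were drawn independently of each other, so these simulations could not show list calls that arise from correlation between genes. Changed genes of all sizes were called together, and passing the threshold needs a smaller unadjusted p where fewer genes change. The shares recovered thus do not hold for comparisons with few changed genes.

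Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter or a filter of 1 CPM in 5 libraries, fits of the 2 groups compared only, 2 surrogate variables (sva 3.50.0), the choroid plexus list as a covariate, adjusted p under 0.01 or 0.1, the deposited RPKM values with a pseudocount of 0.1 or 1 and with or without a minimum of 0.1, and leaving out each library in turn. For the lists, fry and camera on voom values were run as well. Alternatives chosen after seeing the data left out 2 control libraries of 5 months that stood apart from the rest, used the immediate early gene or ribosomal protein list as a covariate, or rebuilt RPKM from the counts. No sample and no column of the deposited tables was left out of the tests as reported.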

Results

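Gene expression was measured by RNA sequencing in 24 libraries from the brain hemisphere of male C57BL/6 mice kept in control or enriched housing. At 5 months of age there were 7 control and 5 enriched libraries, and at 24 months 6 control and 6 enriched libraries. Total counts ran from 16.4 M to 41.7 M in the 5-month controls (median 22 M), from 22.8 M to 29.7 M in the 5-month enriched mice (median 25.7 M), from 20.4 M to 74.4 M in the 24-month controls (median 24.5 M) and from 20.3 M to 39.8 M in the 24-month enriched mice (median 27.4 M). A hemisphere holds cortex, hippocampus, striatum, thalamus and further regions, so each value is an average over many neuronal, glial and vascular cell types. The title of the series states only that brains were sequenced after enrichment, and the comparisons below follow from the 4 groups.

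Control libraries 4 and 6 of 5 months stood apart from all other libraries. They lay at 51.1 and 29.1 on the first principal component, which held 17.6% of the variance, while no other library exceeded 5.82. Mitochondrial transcripts made up 6.85% and 5.99% of their counts, against at most 4.66% elsewhere. Set against the other 5 controls of that age, the mean log2 CPM averaged over both libraries was 0.62 higher for ribosomal protein genes and 0.28 higher for microglia markers. It was 0.68 lower for the clustered protocadherins, cell surface proteins of neurons, 0.44 lower for presynaptic genes and 0.44 lower for endothelial markers. Both libraries are among the 5-month controls of the comparisons that use this group and enter the others through the shared estimate of the spread, and the counts without them are given where they differ.

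**Figure D1:**
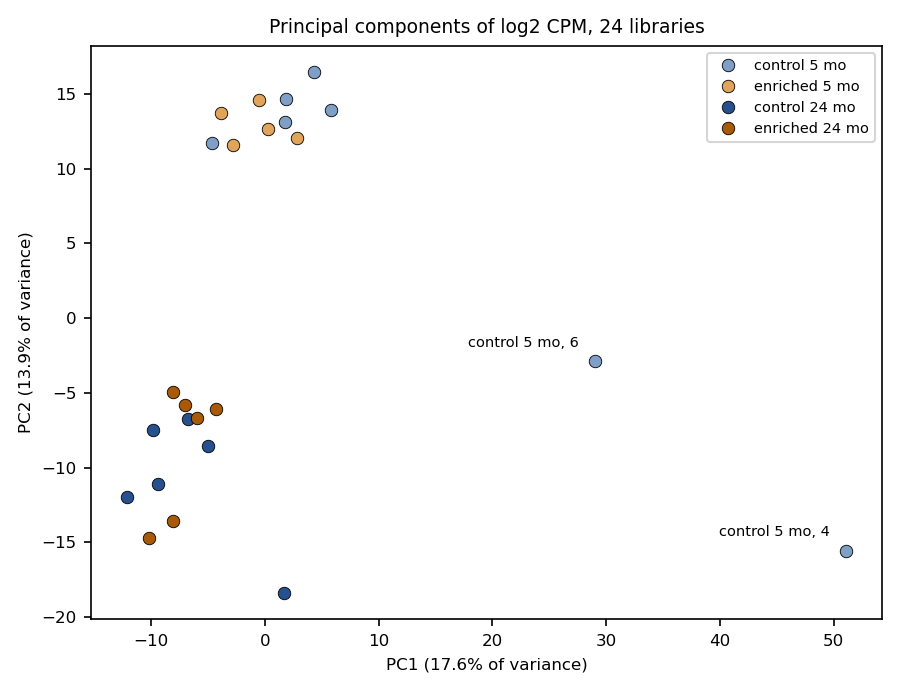
Scores of the 24 libraries on principal components 1 and 2 of log2 CPM (arbitrary units, with 17.6% and 13.9% of the variance), each point 1 library and each colour 1 of the 4 groups. The 2 points apart from the rest are control libraries 4 and 6 of 5 months, at 51.1 and 29.1 on the first component.

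The comparison of enriched with control mice at 5 months asks what enriched housing does to the young adult brain. Crhbp, which encodes the binding protein of corticotropin-releasing hormone, rose from 11.9 ± 0.813 CPM in controls (SD, n = 7) to 14.8 ± 0.236 CPM in enriched mice (SD, n = 5), with enriched libraries from 14.6 to 15.1 and controls from 10.6 to 12.9. Plekha2, which encodes a phosphoinositide-binding adaptor protein, rose from 19.2 ± 1.42 to 24.2 ± 1.16 CPM, also with every enriched library above every control. Another 5 genes fell, among them Dnajb1, a co-chaperone of the heat shock response, from 87.1 ± 5.11 to 72.3 ± 3.99 CPM, and Stk40, a serine/threonine kinase-like protein, from 49.6 ± 3.33 to 37.3 ± 4.62 CPM. Mknk2, a kinase of the translation initiation factor eIF4E, fell from 52.9 ± 4.20 to 42.1 ± 4.15 CPM. Jmjd6, a lysyl hydroxylase of nuclear proteins, fell from 28.9 ± 3.0 to 22.4 ± 2.15 CPM, and Phf21b, a PHD finger protein, fell by a log2 change of -0.40 (SE 0.07).

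These 7 genes, 2 higher and 5 lower, were all that edgeR called out of 17410, while 2498 genes had an unadjusted p under 0.05. Random splits of the 5-month libraries gave up to 4597 such genes, so chance is not excluded for that number. Log2 fold changes were 0.30 (SE 0.05, adjusted p = 0.0170) for Crhbp, 0.33 (SE 0.05, adjusted p = 0.0122) for Plekha2 and -0.41 (SE 0.07, adjusted p = 0.0170) for Stk40. Jmjd6 at -0.36 and Phf21b at -0.40 had an adjusted p of 0.0225, and Mknk2 at -0.33 had one of 0.0434. On GRCm38, Crhbp (ENSMUSG00000021680) lies on chromosome 13 at 95431371 to 95444924, Plekha2 (ENSMUSG00000031557) on chromosome 8 at 25039144 to 25102376, Stk40 (ENSMUSG00000042608) on chromosome 4 at 126103957 to 126141029 and Dnajb1 (ENSMUSG00000005483) on chromosome 8 at 83608193 to 83612653. DESeq2 called 71 genes, a fit of the 2 groups alone called 0 with 1411 at an unadjusted p under 0.05, and the fit without control libraries 4 and 6 called 41, which included all 7. Crhbp had a log2 change of -0.10 in the deposited RPKM values. Leaving out single libraries gave 33 genes without enriched library 1, 11 without control 7, 4 without control 5, 2 without control 2 or enriched library 3, and 0 without enriched library 4 or 5, where the adjusted p of Crhbp and Plekha2 was 0.0785 and 0.0516. Stk40 lost its call without control 2 and enriched libraries 3, 4 and 5 (adjusted p = 0.0540, 0.127, 0.166 and 0.0807), and Dnajb1, Jmjd6 and Phf21b without these and control 5 (up to 0.198, without enriched library 4). Mknk2 lost it in 16 of 24 such fits, with an adjusted p from 0.0536 without control 2 of 24 months to 0.247 without enriched library 4 of 5 months.

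Gene lists showed shifts at 5 months that no list test with an estimated correlation called. Immediate early genes, which neurons transcribe within minutes of activity, had 24 of 24 tested members lower in enriched mice, with 0 past the threshold over all genes and 22 lower adjusted over the list alone (camera adjusted p = 3.27e-16, and adjusted p = 0.468 with an estimated correlation). Their median log2 change was -0.54. Other splits of the 5-month libraries gave this list a camera adjusted p as low as 6.92e-32. Among them, Arc, a synaptic plasticity protein, had 322 ± 62.7 CPM in controls (SD, n = 7) and 139 ± 81.3 CPM in enriched mice (SD, n = 5), a log2 change of -1.21 (SE 0.35) with an edgeR adjusted p of 0.183. Egr3, Gadd45b, Fosb and Maff stood at -0.31, -0.55, -0.58 and -0.74. Mean levels of the list differed by -0.53 between the groups (exact permutation p = 0.0265, adjusted p = 0.387 over the measures compared). They were 5.64 to 5.74 in control libraries 1, 2 and 3 and 4.90 to 5.18 in the other controls. In enriched mice they were 5.15 and 5.08 in libraries 1 and 2 and 4.55 to 4.62 in the others, so both groups overlapped. The labels number the samples of each group in 1 block, so housing is confounded with any handling that followed these numbers.

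Olfactory bulb markers had 9 of 9 tested members higher in enriched mice, 0 past the threshold over all genes and 6 adjusted over the list alone (camera adjusted p = 1.60e-06, and adjusted p = 0.468 with an estimated correlation). Sp8, a transcription factor of bulb interneurons, stood at 0.63, Th, the rate-limiting enzyme of dopamine synthesis, at 0.33, and Tbx21, a transcription factor of mitral cells, at 1.39. Cholesterol synthesis genes had 17 of 20 members lower and 3 of them past the threshold adjusted over the list alone, with Msmo1 at -0.22 and Mvd at -0.30 (camera adjusted p = 2.18e-04, and adjusted p = 0.496 with an estimated correlation). Heat shock and chaperone genes had 9 of 15 members lower, Dnajb1 past the threshold over all genes and 5 members lower adjusted over the list alone (camera adjusted p = 0.0405, and adjusted p = 0.588 with an estimated correlation). This list call was lost without controls 2, 5 and 7 (adjusted p = 0.0504, 0.221 and 0.158) and enriched libraries 1, 3 and 5 (0.0817, 0.130 and 0.0739). Hspa1a and Hspa1b, near-identical inducible chaperones, stood at -0.42 and -0.58.

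Several further lists moved together with control libraries 4 and 6. Ribosomal protein genes had 76 of 78 members lower in enriched mice and 0 past either threshold (camera adjusted p = 4.74e-15, and adjusted p = 0.496 with an estimated correlation). Presynaptic genes had 21 of 22 members higher (camera adjusted p = 4.77e-06, and adjusted p = 0.496 with an estimated correlation), and pan-neuronal markers 13 of 13 (9.70e-04, and adjusted p = 0.496 with an estimated correlation). Clustered protocadherins had 48 of 54 members higher (camera adjusted p = 7.05e-06, adjusted p = 0.588 with an estimated correlation, and 0.0555 without control library 4). Without both libraries the adjusted p of these 4 lists was 0.0552, 0.203, 0.467 and 0.450, and the protocadherins lay in the opposite direction. In all, camera called 12 lists higher and 7 lower, and 8 of these 19 kept their call and direction without both libraries. Choroid plexus markers were not called (adjusted p = 0.524, and adjusted p = 0.896 with an estimated correlation), and Ttr, the transthyretin gene of that tissue, stood at -0.15. Gfap of astrocytes, C4b, Bdnf, Mbp of myelin and Dcx of immature neurons did not pass either, at -0.18, -0.10, -0.18, -0.27 and 0.10.

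**Figure D2:**
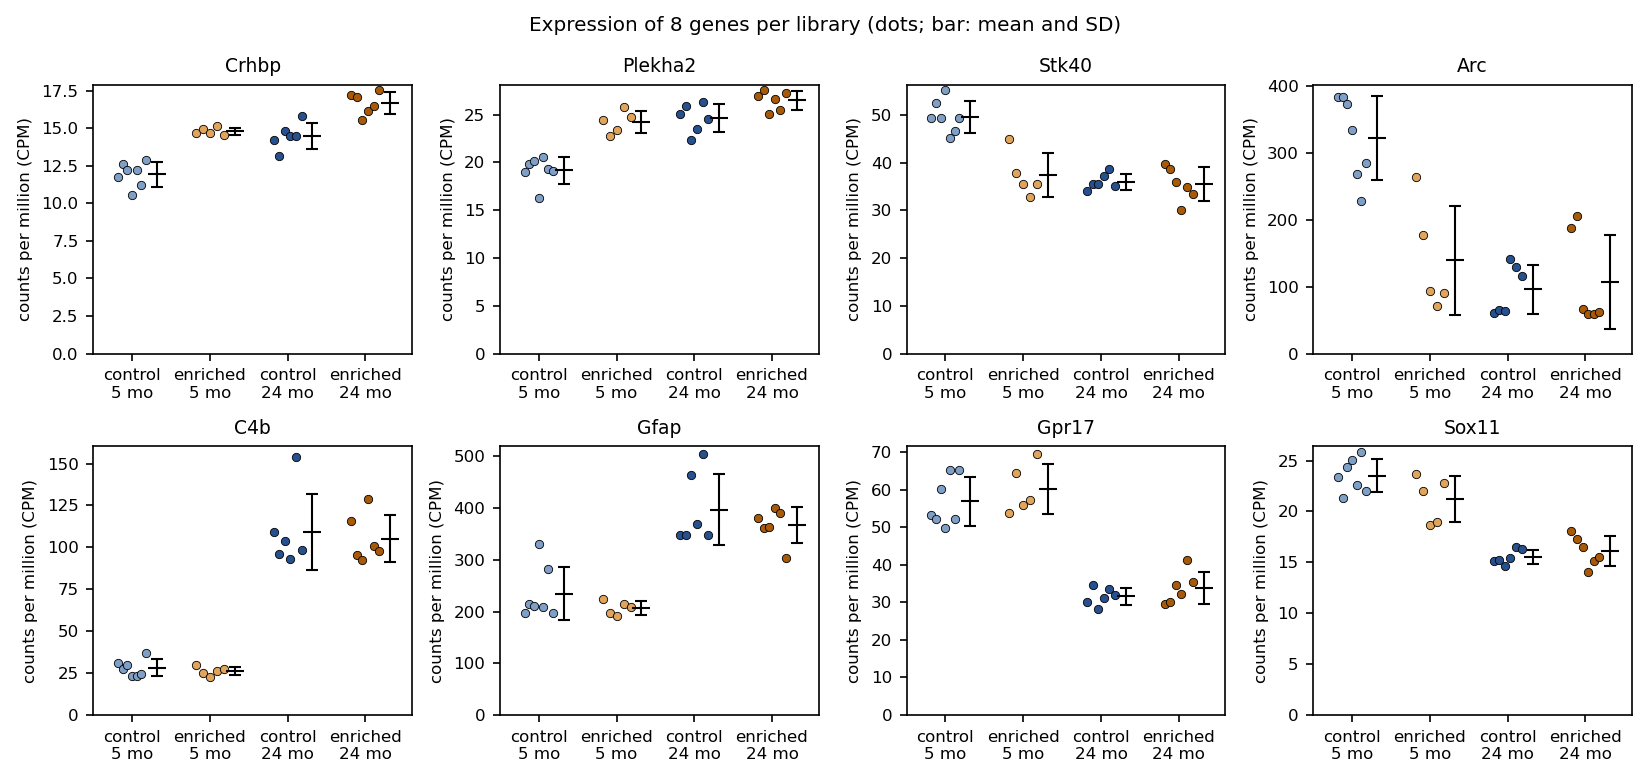
CPM per library of 8 genes in the 4 groups, each dot 1 library and the line and bar the mean and SD (5-month controls n = 7, 5-month enriched n = 5, 24-month controls n = 6, 24-month enriched n = 6). Crhbp ran from 14.6 to 15.1 CPM in 5-month enriched mice and from 10.6 to 12.9 in 5-month controls, and C4b from 92.9 to 154 CPM in 24-month controls and from 23.1 to 37.1 in 5-month controls.

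The same comparison at 24 months asks what enriched housing does to the old brain. No gene passed the threshold there. Of the 5 genes with the smallest p, Avp, the hypothalamic hormone vasopressin, had 10.7 ± 3.09 CPM in controls (SD, n = 6) and 16.1 ± 1.57 CPM in enriched mice (SD, n = 6), a log2 difference of 0.60 (SE 0.14). Vip, a peptide of a class of interneurons, stood at 0.27 (SE 0.06) and Crhbp at 0.20 (SE 0.05), with 14.5 ± 0.860 CPM in controls and 16.7 ± 0.746 CPM in enriched mice. Pard3b, a cell polarity protein, stood at -0.36 (SE 0.08) and Kif13b, a kinesin motor, at -0.23 (SE 0.05).

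The adjusted p of all 5 was 0.915 in edgeR, which called 0 of 17410 genes. Unadjusted p-values under 0.05 were found for 528 genes with edgeR, 585 with DESeq2 and 575 with limma-voom, against 870.5 by chance, and the latter tools called 0 genes as well. Gfap, C4b, Bdnf, Fos and Arc stood at -0.11, -0.06, 0.12, 0.07 and 0.15. In the simulations before use, 74% of genes with a 1.5-fold change were recovered in this comparison, among 163 calls in all. Passing the threshold needs a smaller unadjusted p where fewer genes change. That share thus overstates the power to detect a few changed genes, which was not simulated.

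Camera called 4 lists higher and 9 lower at 24 months, and none with an estimated correlation. The lower lists were not confined to immune genes, as reactive astrocyte, myelin, fibroblast and extracellular matrix lists were among them. These lost their call without some single library of 24 months. The adjusted p was 0.739 for reactive astrocyte genes without control 5 and 0.117 for myelin markers without control 3. It was 0.0749 for extracellular matrix genes without control 2 and 0.0502 for fibroblast markers without enriched library 4. MHC class II genes, which present antigen on microglia and macrophages, had 7 of 7 members lower in enriched mice, 0 past the threshold over all genes and 4 adjusted over the list alone (camera adjusted p = 3.23e-07, and adjusted p = 0.169 with an estimated correlation). H2-Ab1 and H2-Eb1 both stood at -0.49, H2-Aa at -0.43 and Cd74, the invariant chain, at -0.37 with 18.2 ± 3.27 CPM in controls and 14.2 ± 1.95 CPM in enriched mice. The mean of this list differed by -0.29 (exact permutation p = 0.0130, adjusted p = 0.283). Interferon-stimulated genes had 28 of 30 members lower and 0 past either threshold, with Trim30a at -0.29 and Irf9 at -0.19 (camera adjusted p = 3.64e-05, and adjusted p = 0.619 with an estimated correlation). Microglia markers had 17 of 18 members lower, with Cx3cr1 at -0.14 and Sall1 at -0.19 (camera adjusted p = 2.46e-04, adjusted p = 0.619 with an estimated correlation, and 0.117 without control library 3). Glucocorticoid-responsive genes had 13 of 16 members higher, with Fkbp5, a co-chaperone of the steroid receptor, at 0.31 (camera adjusted p = 3.02e-04, and adjusted p = 0.619 with an estimated correlation). Hypothalamic neuropeptides had 8 of 10 members higher, with Avp at 0.60 and Hcrt, the orexin precursor, at 0.29 (camera adjusted p = 0.00360, and adjusted p = 0.169 with an estimated correlation).

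Neurogenesis and proliferation genes had 15 of 19 members lower in enriched mice at 24 months and 0 past either threshold (camera adjusted p = 0.0186, and adjusted p = 0.169 with an estimated correlation). Their mean level differed by -0.14 (exact permutation p = 0.00649, adjusted p = 0.283). That list call was lost without control libraries 3 and 5 of 24 months (adjusted p = 0.0662 and 0.114), enriched library 6 of that age (0.1055), and controls 2 and 4 of 5 months (0.0600 and 0.0551). Olfactory bulb markers had 8 of 9 members lower at this age, opposite to 5 months, and 0 past either threshold (camera adjusted p = 0.0434, and adjusted p = 0.783 with an estimated correlation). Their mean differed by -0.25 (exact permutation p = 0.0346, adjusted p = 0.424). Their list call was lost without control 2 of 5 months (adjusted p = 0.0502), controls 4, 5 and 6 (0.0760, 0.166 and 0.0576) and enriched libraries 2, 4 and 5 of 24 months (0.193, 0.155 and 0.0672).

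Averaged over both ages, the enrichment effect was higher for Crhbp and Plekha2 and lower for Baz1a. Crhbp rose by a log2 change of 0.25 (SE 0.03, adjusted p = 0.00168) and Plekha2 by 0.22 (SE 0.04, adjusted p = 0.0158), and both kept their call without any single library. Baz1a, a subunit of chromatin remodelling complexes, fell by a log2 change of -0.42 (SE 0.07, adjusted p = 0.0292), from 5.46 ± 0.487 to 3.86 ± 0.388 CPM at 5 months and from 4.01 ± 0.316 to 3.22 ± 0.646 CPM at 24 months. It lies on chromosome 12 at 54892989 to 55014348 (ENSMUSG00000035021). Inhibitory neuron markers had 11 of 15 members higher, 0 past the threshold over all genes and 4 adjusted over the list alone (camera adjusted p = 4.62e-05, and adjusted p = 0.566 with an estimated correlation). Its mean level at 5 months was 5.35 in enriched mice, 5.22 in all controls and 5.29 in the controls other than libraries 4 and 6, which stood at -0.34 and -0.14 against them, and the averaged call stayed without both. Npy, Vip and Sst, peptides of separate interneuron classes, stood at 0.20, 0.16 and 0.11. MHC class II genes had 7 of 7 members lower and 2 of them adjusted over the list alone (camera adjusted p = 1.66e-04, and adjusted p = 0.581 with an estimated correlation).

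These 3 genes were the edgeR calls for the average, with 1735 genes at an unadjusted p under 0.05, and DESeq2 called 30. Splits that shuffled housing within each age gave up to 3317 genes at that unadjusted p. Baz1a lost its call in 12 of the 24 fits without 1 library, with an adjusted p from 0.0514 without control 1 of 5 months to 0.124 without enriched library 5 of 24 months, and the count was 5 without control library 6 or 7 of 5 months and 6 without enriched library 1 of 5 months. Without both control libraries 4 and 6 it was 24, which included the 3.

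Ageing in control housing, from 5 to 24 months, changed more genes than either housing comparison called, and asks what the old brain looks like without enrichment. C4b, a complement component made by glia, rose from 28.1 ± 5.04 CPM at 5 months (SD, n = 7) to 109 ± 22.7 CPM at 24 months (SD, n = 6), a log2 change of 1.96 (SE 0.12, adjusted p = 2.09e-11). Gpnmb, a glycoprotein of lipid-laden phagocytes, rose from 2.10 ± 0.395 to 6.20 ± 1.54 CPM, and Gfap, the intermediate filament of astrocytes, from 234 ± 51.7 to 397 ± 69.2 CPM. Gpr17, a receptor of newly forming oligodendrocytes, fell from 56.9 ± 6.48 to 31.6 ± 2.34 CPM, a log2 change of -0.85 (SE 0.08, adjusted p = 1.53e-07). Bdnf, a neurotrophin, fell by a log2 change of -0.50 (adjusted p = 6.99e-06) and Arc by -1.75 (SE 0.34, adjusted p = 0.00124). In enriched mice Bdnf and Arc stood at -0.20 and -0.39 with age and did not pass. For both genes, handling particular to the 5-month controls cannot be told apart from age.

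Among the 10 rising genes with the smallest p were also Lag3, an inhibitory immune receptor (0.98), Itgb2, a leukocyte integrin (0.82), Mpeg1, a pore-forming protein of macrophages (0.65), Abca8a, a lipid transporter (0.76), Zc3hav1, an antiviral RNA-binding protein (0.53), Pcdhb9, a clustered protocadherin (0.82), and Spag6, a protein of motile cilia (1.07). The 10 falling genes included the co-chaperones Dnajb1 (-0.52, adjusted p = 3.86e-08) and Dnajb5 (-0.48), Sox11 and Sox4, transcription factors of immature neurons (-0.59 and -0.55), the small GTPase Rnd3 (-0.47), the activity-induced transcription factor Egr3 (-0.58) and the receptor Gpr3 (-0.82). C4b (ENSMUSG00000073418) lies on chromosome 17 at 34728380 to 34743882 and Gpr17 (ENSMUSG00000052229) on chromosome 18 at 31942997 to 31949636. C4a, a near-identical neighbour that can exchange reads with C4b, stood at -0.32 (adjusted p = 0.188).

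In all, 857 genes rose and 716 fell with age in controls, with a median absolute log2 change of 0.32 and 90 genes past a 2-fold change. Of the 17410 genes, 4142 had an unadjusted p under 0.05, while other splits of these libraries gave up to 4837 such genes. Ttr at -0.04, Mbp at 0.04 and Dcx at -0.00 did not pass. The deposited RPKM values, whose median over all genes was itself shifted by 0.23, gave 6 genes, a fit of the 2 groups alone 836, the ribosomal protein covariate 2444 and the choroid plexus covariate 3044. Fos, at -1.04 (SE 0.30, adjusted p = 0.0268), lost its call without control libraries 1, 2 or 3 of 5 months (0.0522, 0.0556 and 0.0535) or 1, 2 or 3 of 24 months (0.0648, 0.0588 and 0.0584).

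Glial and immune lists rose together with age. Disease-associated microglia genes, a programme of phagocytic microglia, had 16 of 22 members higher over all genes and 20 adjusted over the list alone, and held with an estimated correlation (adjusted p = 0.00125). Clec7a, a fungal recognition receptor, rose by a log2 change of 3.18 (SE 0.31) and Itgax, an integrin of activated microglia, by 2.51 (SE 0.29). Reactive astrocyte genes had 12 of 18 members higher and 1 lower, or 15 higher and 1 lower adjusted over the list alone, with C3 at 2.24 and Serpina3n at 1.21 (adjusted p = 0.00125 with an estimated correlation). Complement genes had 8 of 15 members higher and 10 adjusted over the list alone, with C3ar1 at 0.82 and C1qc at 0.37 (adjusted p = 2.74e-04 with an estimated correlation). Interferon-stimulated genes had 19 of 30 higher and 23 adjusted over the list alone, with Ifit3 at 0.86 and Lgals3bp at 0.76 (adjusted p = 0.0246 with an estimated correlation). Lysosomal genes had 10 of 20 higher and 15 adjusted over the list alone, with the cathepsins Ctss at 0.64 and Ctsz at 0.40 (adjusted p = 0.0122 with an estimated correlation).

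MHC class I genes had 12 of 14 members higher with age in controls and 14 adjusted over the list alone, with B2m at 0.52 and H2-D1 at 0.75 (camera adjusted p = 5.88e-16, and adjusted p = 0.0513 with an estimated correlation). MHC class II genes had 5 of 7 higher and 6 adjusted over the list alone, with Cd74 at 0.74 (camera adjusted p = 3.15e-05, and adjusted p = 0.0911 with an estimated correlation). T cell and B cell markers had 2 of 7 members higher and 3 adjusted over the list alone, with Cd8a of cytotoxic T cells at 1.41 (camera adjusted p = 0.0218, and adjusted p = 0.387 with an estimated correlation). That list call was lost without control libraries 3 and 5 of 24 months (adjusted p = 0.151 and 0.321) and enriched libraries 3 and 5 of 24 months (0.0607 and 0.101), while the mean level differed by 0.61 (exact permutation p = 0.00874, adjusted p = 0.0329). Cd8a lost its call without control libraries 5 and 7 of 5 months (0.0574 and 0.0578). The other member that passed, Igkc, lost it without control libraries 2, 3, 4, 5, 6 and 7 of 5 months (0.0677, 0.0735, 0.0537, 0.0678, 0.0754 and 0.0680) and 2, 3 and 5 of 24 months (0.0877, 0.0806 and 0.171). Blood cell markers had a mean 0.69 higher as well (exact permutation p = 0.0554, adjusted p = 0.136), without a call (camera adjusted p = 0.0640). A part of this lay in control library 1 of 24 months, at 3.67 against 2.0 to 2.47 in the others of its group. Microglia markers moved both ways, with 7 of 18 members higher and 1 lower, or 8 higher and 1 lower adjusted over the list alone. Ctss and Cx3cr1 rose by 0.64 and 0.34 and Fcrls fell by a log2 change of -0.59 (camera adjusted p = 1.50e-05, and adjusted p = 0.273 with an estimated correlation). Clustered protocadherins had 19 of 54 members higher and 24 adjusted over the list alone (camera adjusted p = 1.02e-16, and adjusted p = 0.245 with an estimated correlation), and this list was 0.68 lower in control libraries 4 and 6 of 5 months than in the other controls of that age.

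Activity, chaperone and growth lists fell with age in controls. Immediate early genes had 18 of 24 members lower over all genes and 22 adjusted over the list alone, with Homer1 at -0.63 and Fosl2 at -0.81 (adjusted p = 0.0401 with an estimated correlation). Their mean log2 CPM ran from 4.90 to 5.74 in 5-month controls and from 4.46 to 4.82 in 24-month controls. In enriched mice it ran from 4.55 to 5.15 at 5 months and from 4.42 to 5.14 at 24 months. The enrichment comparison at 5 months uses the same 5-month controls, so handling particular to that group cannot be told apart from age here or from enrichment there. Heat shock and chaperone genes had 10 of 15 lower by both adjustments, with Hspa1a at -0.64 (adjusted p = 0.0246 with an estimated correlation). Neurogenesis and proliferation genes had 4 of 19 lower and 5 adjusted over the list alone, with Sox11, Sox4 and the topoisomerase Top2a at -0.98 (adjusted p = 0.00245 with an estimated correlation). Thyroid hormone responsive genes had 1 of 10 lower and 5 adjusted over the list alone, with Dio2, the enzyme that activates the hormone, at -1.13 (adjusted p = 0.0246 with an estimated correlation). Unfolded protein response genes had 8 of 18 lower and 10 adjusted over the list alone, with Atf4 at -0.30 (camera adjusted p = 1.44e-05, and adjusted p = 0.0625 with an estimated correlation). Replication-dependent histone genes had 2 of 11 lower by both adjustments (camera adjusted p = 0.00413, and adjusted p = 0.426 with an estimated correlation). Camera called 25 lists in all, 14 higher and 11 lower, and 9 of them with an estimated correlation.

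**Figure D3:**
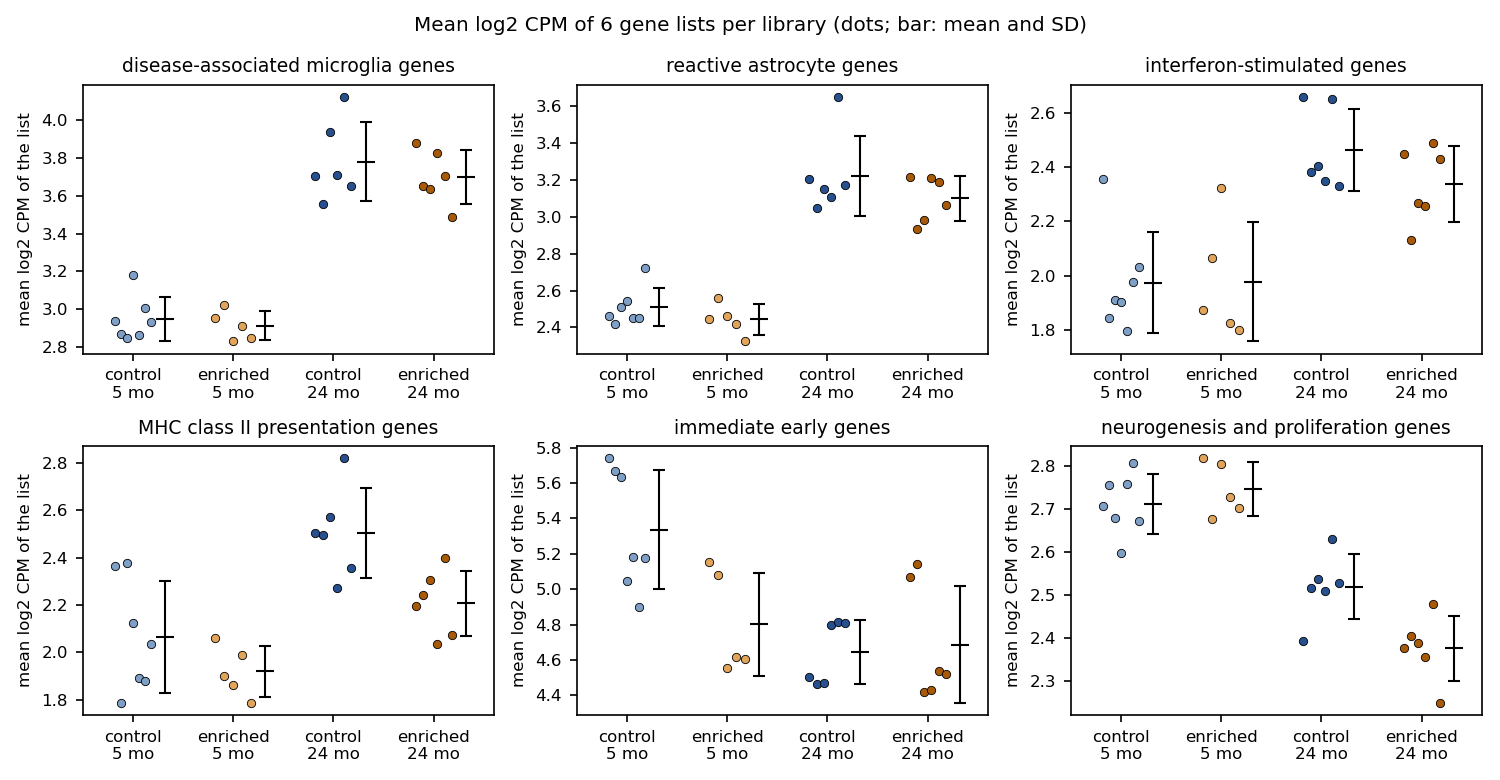
Mean log2 CPM per library of 6 gene lists in the 4 groups, each dot 1 library and the line and bar the mean and SD. The lists of disease-associated microglia and reactive astrocyte genes were 0.83 and 0.71 higher at 24 than at 5 months in controls, and immediate early genes 0.69 lower.

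The comparison of 24 with 5 months among enriched mice asks the same of mice given enrichment. The length of their stay was not given, so it may differ between the ages, and the mice need not have aged in enrichment. C4b rose from 26.2 ± 2.59 CPM at 5 months (SD, n = 5) to 105 ± 14.1 CPM at 24 months (SD, n = 6), a log2 change of 2.0 (SE 0.13, adjusted p = 2.31e-10), and Gfap rose from 207 ± 13.9 to 367 ± 34.6 CPM. Gpr17 fell from 60.2 ± 6.63 to 33.8 ± 4.33 CPM, a log2 change of -0.83 (SE 0.09, adjusted p = 1.55e-06). Apod, a lipid carrier of glia, rose by a log2 change of 0.73, the nuclear long noncoding RNA Neat1 by 0.78 and Ppl, a cytoskeletal linker, by 0.88. Zc3hav1, Itgb2, Mpeg1, Lag3 and Pcdhb9 rose here too, by 0.54, 0.68, 0.55, 0.78 and 0.88.

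Among falling genes were Sox4 (-0.54) and Sox11 (-0.40), Nrep, a regulator of neuronal regeneration (-0.47), Marcksl1, an actin-binding protein of growing neurites (-0.36), and Nectin3, an adhesion protein of synapses (-0.33). Bdnf at -0.20, Fos at -0.19 and Arc at -0.39 did not pass (adjusted p = 0.116, 0.858 and 0.679). In all, 326 genes rose and 134 fell, with a median absolute log2 change of 0.40 and 50 genes past a 2-fold change, and 2709 of 17410 genes had an unadjusted p under 0.05. The count of 460 was 773 without control library 4 of 5 months, 264, 284 and 248 without enriched libraries 2, 3 and 4 of 5 months, and 290 and 274 without enriched libraries 1 and 6 of 24 months, and a fit of the 2 groups alone gave 1132. It was 1332 without control libraries 4 and 6 of 5 months, which enter this comparison only through the shared estimate of the spread, and 2 in the deposited RPKM values.

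Disease-associated microglia genes had 14 of 22 members higher with age in enriched mice and 18 adjusted over the list alone, with Clec7a at 2.82 and Itgax at 2.51 (adjusted p = 2.77e-04 with an estimated correlation). Reactive astrocyte genes had 9 of 18 higher and 11 adjusted over the list alone, with C3 at 1.81 (adjusted p = 5.28e-04 with an estimated correlation). MHC class I genes had 9 of 14 higher and 13 adjusted over the list alone, with H2-D1 at 0.73 (adjusted p = 0.0330 with an estimated correlation). Complement genes had 6 of 15 higher, or 10 higher and 1 lower adjusted over the list alone, with C3ar1 at 0.80 (adjusted p = 2.27e-05 with an estimated correlation). Lysosomal genes had 3 of 20 higher and 9 adjusted over the list alone, with Ctss at 0.54 and Cd68 at 0.56 (adjusted p = 0.0188 with an estimated correlation). Neurogenesis and proliferation genes had 4 of 19 lower and 8 adjusted over the list alone, with Top2a at -1.37 and Dpysl3, a growth cone protein, at -0.37 (adjusted p = 4.18e-05 with an estimated correlation). Interferon-stimulated genes had 8 of 30 higher and 15 adjusted over the list alone, with Ifit3 at 0.80 (camera adjusted p = 7.13e-16, and adjusted p = 0.0558 with an estimated correlation). T cell and B cell markers had 1 of 7 higher, Cd8a, which lost its call without enriched library 3 of 5 months (0.0512), and 4 adjusted over the list alone (camera adjusted p = 0.00398, adjusted p = 0.263 with an estimated correlation, 0.0821 without enriched library 5 and 0.0532 without control library 3 of 24 months). Immediate early genes were called here too, but lost their call without enriched libraries 1 or 2 of 5 months or 3, 4, 5 or 6 of 24 months. The camera adjusted p was then up to 0.353, without enriched library 1 of 5 months. Camera called 23 lists, 13 higher and 10 lower, and 7 with an estimated correlation.

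**Figure D4:**
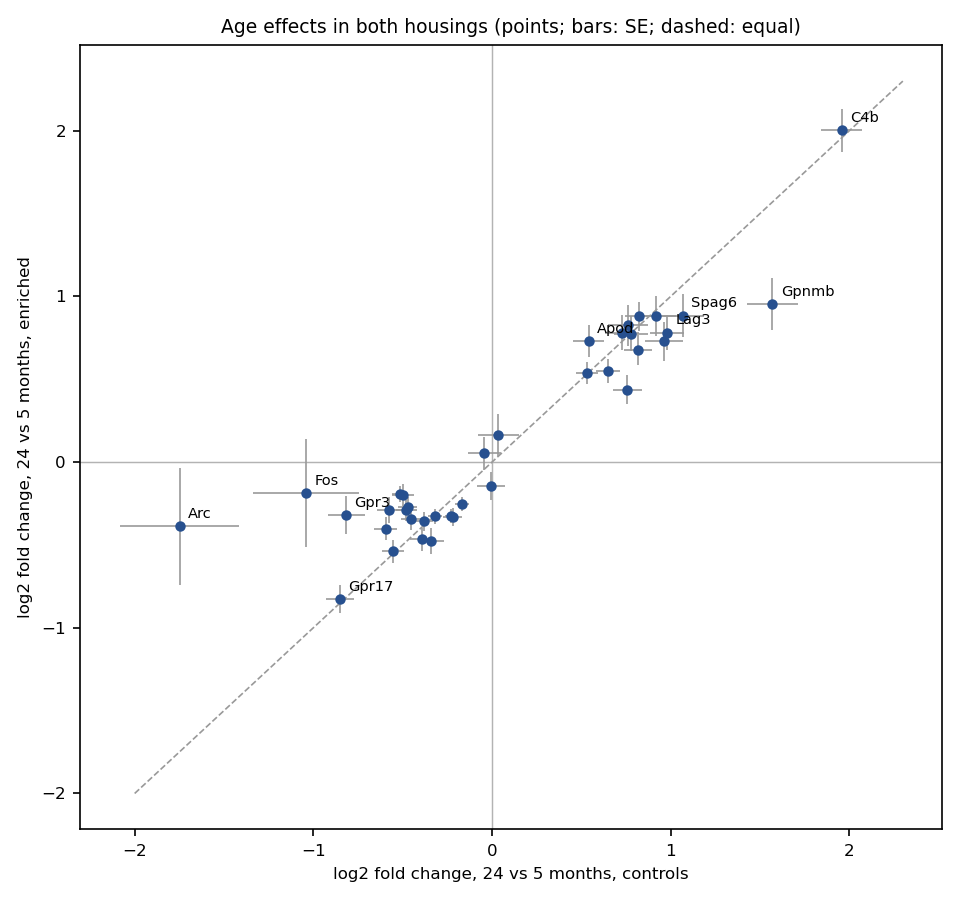
Log2 fold change from 5 to 24 months of 37 genes in controls (x axis) and in enriched mice (y axis), with bars of 1 SE and a dashed line of equal change. C4b lies at 1.96 and 2.0, Gpr17 at -0.85 and -0.83, and Arc at -1.75 and -0.39.

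Both age effects, which share no library, were alike in direction. Of the 460 genes called in enriched mice, 446 had the same sign in controls, and of the 1573 called in controls 1463 had the same sign in enriched mice. Genes that rose in both numbered 236, against 16 for independent lists, genes that fell in both 72, against 5.51, and 0 were called in opposite directions. Across genes, which are not independent replicates, the log2 changes had a Spearman correlation of 0.411 and a Pearson correlation of 0.509.

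Whether the enrichment effect differs between the ages is the question of the interaction, and no gene passed it. Dnajb1 had an enrichment effect higher at 24 than at 5 months by a log2 difference of 0.32 (SE 0.07) and Jmjd6 by 0.43 (SE 0.09), each with an adjusted p of 0.597. Arc stood at 1.36 (SE 0.48, adjusted p = 0.821), Fos at 0.85 and Bdnf at 0.30 (SE 0.09, adjusted p = 0.807), while C4b at 0.04 (SE 0.17) and Gfap at 0.06 (SE 0.16) differed less than their SE. Immediate early genes had 24 of 24 members with a positive difference, 0 past the threshold over all genes and 8 adjusted over the list alone, with a median of 0.63 (camera adjusted p = 7.69e-18, and adjusted p = 0.357 with an estimated correlation). Splits that shuffled housing within each age gave this list a camera adjusted p as low as 3.58e-40. The interaction equals the age effect in enriched mice minus that in controls, so genes called in only one of these housings, Bdnf and Arc among them, were not shown to age differently.

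For the interaction edgeR called 0 of 17410 genes, with 5.58% of them at an unadjusted p under 0.05, DESeq2 called 0 with 1104 genes at that p and limma-voom 0 with 947. Without control libraries 4 and 6 of 5 months edgeR called 2 genes, Dnajb1 at 0.34 and Fosb at 0.92. Of genes with a 1.5-fold difference, 66% were recovered in simulated data, among 144 calls in all. This share too overstates the power to detect a few changed genes.

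Across genes, the enrichment effects at 5 and 24 months had a Spearman correlation of 0.124, or 0.264 for genes with a mean log2 CPM of at least 3, and a Pearson correlation of -0.0318, and on differences of mean log2 CPM the Pearson correlation was 0.0378 (permutation p = 0.690, 1000 relabellings of housing within each age). Crhbp was higher in enriched mice at both ages, by 0.30 and 0.20, while Arc stood at -1.21 and 0.15. The Spearman correlation ran from -0.0109 without control library 3 of 24 months to 0.171 without enriched library 1 and 0.179 without control library 1 of that age, and was 0.0508 without control libraries 4 and 6 of 5 months.

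The last relation asks whether enrichment moves old brains toward the young profile. Of the 1573 genes that changed with age in controls, 1069 (68.0%) had an enrichment effect at 24 months of the opposite sign, and across all genes the Spearman correlation was -0.217 and the Pearson correlation -0.383. For genes with a mean log2 CPM of at least 3 the Spearman correlation was -0.0452. Both contrasts contain the 24-month controls with opposite sign, so a negative value arises without any effect. The values were therefore set against 100 simulations with no enrichment effect, both on differences of mean log2 CPM. The Spearman correlation of -0.202 was weaker than in all simulations (-0.253 to -0.222), the Pearson correlation of -0.323 stronger (-0.279 to -0.210), the covariance of -0.00859 within their range (-0.00944 to -0.00690) and the opposite share of 66.9% above it (47.4% to 52.4%). For that share the genes had been chosen by their age effect in the observed controls, a selection that the simulations do not repeat. Simulated genes were also drawn independently of each other, so the simulated ranges are too narrow where genes move together. No conclusion is drawn from values outside them. When the 24-month controls were split so that no library was shared, the Spearman correlation averaged 0.0166 over 20 splits (from -0.0851 to 0.130) and the Pearson correlation -0.0443 (from -0.124 to 0.0460), with p = 0.498 for the latter in an exact permutation test over 924 relabellings. MHC class II and interferon-stimulated genes were among the lists higher with age in controls and lower with enrichment at 24 months. Neurogenesis and proliferation genes were lower in both, and none of these 3 lists was called for enrichment with an estimated correlation, nor MHC class II for age in controls (adjusted p = 0.0911).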

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

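The comparisons with other splits of the libraries and the test of a gene length trend were planned before the data were examined, while the tests of immediate early gene state, of the pair of divergent control libraries and of neuron share and depth were chosen after the results were seen.

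At 5 months Crhbp and Plekha2 were higher and Dnajb1, Stk40, Jmjd6, Phf21b and Mknk2 lower in enriched than in control mice. The 24-month controls lay on the same side of the 5-month controls for Crhbp (13.2 to 15.8 against 10.6 to 12.9 CPM) and Stk40 (34.0 to 38.65 against 45.2 to 55.1). Across genes this effect had a Spearman correlation of 0.478 with age in controls, but sharing the 5-month controls alone gives a positive value. Handling particular to the 5-month controls cannot be told apart from enrichment. The number of called genes was above that of other splits, since 1 of 100 splits of these libraries, the real one, called as many as 7 genes and the highest other called 2. With 100 splits the share cannot fall below 1 in 100, so chance is unlikely for this number but not excluded. Control libraries 4 and 6 do not account for these calls, because all 7 genes passed without them (adjusted p from 0.00309 to 0.0183). Fold changes of the 7 genes were then a median of 0.960 times those reported. With the immediate early gene level as a covariate, the 2 higher genes passed with a median of 1.14 times their fold change (0.32 before, 0.36 after), which argues against that state as their source. For the 5 lower genes the ratio was 0.728 (median log2 change -0.36 before, -0.27 after) and 0 of 5 passed, at adjusted p-values up to 0.0825, so a lower activity state and a separate effect of enrichment cannot be told apart: the covariate itself moves with housing.

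Gene lists called between housings, such as immediate early, olfactory bulb and ribosomal protein genes at 5 months and MHC class II genes at 24 months, were more numerous than the genes. Chance cannot be excluded for their number, since 31 of 100 splits called at least the real 19 lists at 5 months (highest other 28), 61 at least the real 13 at 24 months (highest other 28) and 44 at least the real 16 for the average (highest other 27). With an estimated correlation 0 lists were called in these comparisons. With the preset correlation of 0.01, other splits of the same libraries called a median of 15, 14 and 15 lists. The preset is thus too low for these data, and its p-values overstate the list differences. Any handling that followed the sample numbers, which run in 1 block per group, stays open. At 5 months control libraries 4 and 6 may account for a part of the list calls, as 8 of the 19 lists stayed called in the same direction without both, 3 turned and 8 no longer passed, while 13 stayed without library 4 alone, 16 without library 6 alone and at least 15 without any other single library. An effect of enrichment on immediate early, olfactory bulb and cholesterol synthesis genes, which are among the lists that stayed called, remains open as a biological explanation, though olfactory bulb markers were called in the opposite direction at 24 months (-0.25, exact permutation p = 0.0346). For these markers a differing share of bulb in the dissected tissue stays open too and was not tested. At 5 months their mean log2 CPM was 2.43 and 2.60 in control libraries 5 and 6 but 1.47 to 1.89 in the other controls. It was 1.91 in enriched library 2 but 2.42 to 2.98 in the other enriched libraries.

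Control libraries 4 and 6 of 5 months had more ribosomal protein, mitochondrial, microglia, astrocyte and myelin transcripts and fewer protocadherin, presynaptic and vascular transcripts than the other 5 controls, and 22 lists lay over 3 SDs away in both, 6 above and 16 below. A lower share of neurons would raise the markers of all other cell types, yet endothelial markers stood at -0.44 and mural markers at -0.39 while microglia stood at 0.28. A gene length trend leaves most of the pattern, since a median of 0.883 of the list deviations remained without the trend with exon length, but it stays open for some lists, since in library 4 only 0.317 of the deviation of mitochondrially encoded genes, 0.406 of oxidative phosphorylation, 0.427 of microglia and 0.433 of postsynaptic genes remained. A lower depth is excluded as the cause shared by both, because library 6, at 21.6 M counts, had more than 5 other libraries, but it stays open for library 4, which had the fewest of all 24 at 16.4 M. The labels give no biological difference from the other controls to test, and a difference in dissection stays open, since midbrain and brainstem monoamine markers stood at -1.34 and -0.96 and thalamic markers at -0.24 and -0.17 but striatal markers at 0.02 and 0.16, and so do RNA quality and preparation day, for which the labels hold no record.

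For age in controls 1 of 100 splits called at least the real 1573 genes (highest other 455). For age in enriched mice 1 of 100 called at least 460 (highest other 87), so chance is unlikely for both. Other splits can follow age in part, and what sets apart those that called 455 and 87 genes was not tested. Numbers of lists were less distinct, with 16 of 100 splits at or above the real 25 in controls (highest other 30) and 6 of 100 at or above the real 23 in enriched mice (highest other 26), so chance is not excluded for these numbers. For the average over ages 1 of 100 splits called at least 3 genes (highest other 1), which makes chance unlikely, though the margin is narrow. With 0 real calls, all 100 splits were as large for enrichment at 24 months (highest other 0) and for the interaction (highest other 2), and 13 of 100 called at least the real 22 interaction lists (highest other 27).

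Single libraries lay far from the rest of their group in 24 of 252 groups of values, where chance gives about 1 in 20, or 12.6. Among the 24-month controls, library 5 had 74.4 M counts (others 20.4 to 37.9), a reactive astrocyte level of 3.65 (3.05 to 3.21, as mean log2 CPM here and below) and a C4b level of 7.27 (6.54 to 6.77). Library 3 of that group had 5.25% of counts in its top 10 genes (others 4.11% to 4.35%), 4.66% mitochondrial counts (others 3.6% to 3.84%) and an Mbp level of 11.99 (11.54 to 11.68). Its lists stood at 12.19 for mitochondrially encoded genes (others 11.78 to 11.89), 3.82 for ribosomal protein genes (3.56 to 3.62), 9.0 for presynaptic genes (9.13 to 9.19), 2.77 for protocadherins (2.99 to 3.08) and 5.78 for antioxidant and iron genes (5.64 to 5.69). These lists deviated in the same directions in control libraries 4 and 6 of 5 months. Whether a common cause reaches into the 24-month controls was not tested. Library 1 of the 24-month controls stood at 5.23 for endothelial markers (4.75 to 4.88) and 3.67 for blood cell markers (2.0 to 2.47), and library 2 at 0.81 for perivascular macrophage markers (1.09 to 1.12).

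Among the 24-month enriched libraries, library 5 stood at 0.87 for T cell and B cell markers (others -0.20 to 0.20), library 1 at 9.37 for Ttr (8.90 to 9.03) and library 6 at 6.59 for myelin markers (6.72 to 6.79) and 8.25 for Gfap (8.50 to 8.64). Enriched library 1 of 5 months stood at 2.83 for protocadherins (2.80 to 2.81). Among the 5-month controls, library 4 had a median correlation with the other 23 libraries of 0.984 (others 0.990 to 0.993), library 6 stood at 6.51 for striatal markers (6.34 to 6.38) and 1.64 for hypothalamic neuropeptides (1.83 to 1.91), library 7 at 2.72 for reactive astrocyte genes (2.42 to 2.54) and library 1 at 2.36 for interferon-stimulated genes (1.79 to 2.03).

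Camera called 22 lists as different between the enrichment effects at 24 and 5 months, and 0 of them with an estimated correlation, where their adjusted p lay between 0.184 and 0.662, and 11 of the 22 lost their call without some single library. More positive at 24 months were immediate early genes (adjusted p = 7.69e-18), ribosomal protein genes (6.45e-11), oxidative phosphorylation genes (1.73e-04), cholesterol synthesis genes (0.00186), glucocorticoid-responsive genes (0.00207), heat shock genes (0.00354), ependymal markers (0.00521), antioxidant and iron genes (0.0181), circadian clock genes (0.0440) and p53 and senescence genes (0.0440). More negative were olfactory bulb markers (3.10e-09), fibroblast markers (1.51e-08), protocadherins (4.91e-05), extracellular matrix genes (5.31e-05), GABA receptor genes (0.00135), mural cell markers (0.00174), presynaptic genes (0.00279), endothelial markers (0.0195), interferon-stimulated genes (0.0260), dentate gyrus markers (0.0403), oligodendrocyte precursor markers (0.0440) and thalamic markers (0.0440).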

How the results depend on the processing

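Alternatives chosen after seeing the data were those that left out control libraries 4 and 6 of 5 months, used the immediate early gene or ribosomal protein level as a covariate, or rebuilt RPKM from the counts; all others were fixed beforehand. The 7 genes called with enrichment at 5 months kept direction and call with DESeq2, limma-voom, RLE and upper-quartile scaling, both count filters, 2 surrogate variables and the choroid plexus and ribosomal covariates, and so did the 3 genes of the average. With the immediate early covariate 2 of the 7 and 2 of the 3 kept both, and with rebuilt RPKM 7 and 2. Of 86 genes named for age in controls, 85 kept both with DESeq2, 83 with limma-voom, 77 without libraries 4 and 6 and 73 with the immediate early covariate (12 weaker, 1 reversed), and of the 85 testable there 75 did with the 2 groups alone and 76 with rebuilt RPKM. Of 61 for age in enriched mice 61 did with DESeq2 and 60 with limma-voom, and 54 of 60 with rebuilt RPKM. The calls at 24 months stayed at 0 under every alternative run. In simulations at these depths, recovery of genes with a 1.5-fold difference was lowest in the interaction, at 66%, and depth itself was not varied. The shares recovered do not hold for comparisons with few changed genes.

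Counts of genes that moved by over 1.5 times were these; the cause was not tested except where the threshold itself changed. For enrichment at 5 months (7 genes) DESeq2 called 71, the 2 groups alone 0, the 3 RPKM alternatives 0 each, surrogate variables 33, the choroid covariate 69, adjusted p under 0.01 0, under 0.1 36, without libraries 4 and 6 41, with the 2 groups alone as well 53, and the ribosomal covariate 51. For the average (3 genes) DESeq2 called 30, RPKM 0 each, surrogate variables 8, the choroid covariate 15, p under 0.01 1, under 0.1 6, without libraries 4 and 6 24, and the ribosomal covariate 22. For age in controls (1573) the 2 groups alone gave 836, RPKM 6, 1 and 2, the choroid covariate 3044, p under 0.01 572 and the ribosomal covariate 2444. For age in enriched mice (460) the 2 groups alone gave 1132, RPKM 2, 1 and 1, p under 0.01 162, under 0.1 781, without libraries 4 and 6 1332 and the ribosomal covariate 1248. The interaction gave 2 without libraries 4 and 6 and 2 with the ribosomal covariate.

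Called lists moved to 0 with an estimated correlation and 0 with fry for enrichment at 5 months, at 24 months, averaged and the interaction, to 9 with an estimated correlation for age in controls, and to 7 and 12 for age in enriched mice. With the ribosomal covariate 12 lists were called at 5 months and 13 for the interaction, and without libraries 4 and 6 13 for the interaction. Leaving out each library in turn gave 0 to 33 genes at 5 months, 0 at 24 months, 2 to 6 averaged, 1051 to 1749 for age in controls, 248 to 773 for age in enriched mice and 0 for the interaction. Lists then numbered 13 to 23, 11 to 21 (20 without enriched library 1 or 6 and 21 without control library 6 of 24 months), 14 to 21, 23 to 26, 21 to 26 and 15 to 26, and 8 of 19, 8 of 13, 6 of 16, 7 of 25, 3 of 23 and 11 of 22 called lists lost their call in at least 1 such fit.

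The Spearman correlation of enrichment at 24 months with age in controls was -0.0452 for genes with a mean log2 CPM of at least 3, 0.0166 with no shared library, -0.294 without libraries 4 and 6, and -0.287 to -0.161 without single libraries. That of both enrichment effects was 0.264, 0.0508 without libraries 4 and 6, 0.0338 with the immediate early covariate and -0.0109 to 0.179 without single libraries, and that of both age effects was 0.509 without libraries 4 and 6 and 0.366 to 0.494 without single libraries.

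Lists that turned direction had these adjusted p-values. At 5 months with the ribosomal covariate, endothelial 0.905, pan-neuronal 0.831, presynaptic 0.775, extracellular matrix 0.391, oxidative phosphorylation 6.76e-05, ribosomal 0.271 and protocadherin 0.00216; without libraries 4 and 6, extracellular matrix 0.749, oxidative phosphorylation 0.490 and protocadherin 0.450; with the immediate early covariate, immediate early 0.377. For the average, microglia 0.965, ribosomal 0.272 and protocadherin 0.00150 with the ribosomal covariate, protocadherin 0.540 without the libraries and immediate early 0.375 with its own covariate. For age in controls, immediate early 0.811 with its own covariate, oxidative phosphorylation 0.402 and ribosomal 0.0768 without the libraries, and 0.841 and 0.425 with the ribosomal covariate. For the interaction, immediate early 0.502 and cholesterol synthesis 0.690 with the immediate early covariate, presynaptic 0.377 and protocadherin 0.368 without the libraries, and presynaptic 0.150, oxidative phosphorylation 0.484, ribosomal 0.438 and protocadherin 0.101 with the ribosomal covariate. A list turned by its own level as covariate does so by construction, and for the others the cause was not tested.

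In the deposited RPKM values, Crhbp stood at -0.10, -0.10 and -0.10 at 5 months (plus 0.1, plus 1 and plus 0.1 unfiltered). For age in controls, where those values shift the median of all genes by 0.23 and 0.16, Nrn1 stood at 0.0802, 0.0799 and 0.0802, Errfi1 at 0.28, 0.26 and 0.28, Ddit4 at 0.10, 0.10 and 0.10, Dnaja1 at 0.0916, 0.0893 and 0.0916 and Rpl36a at 0.15, 0.14 and 0.15, with the cause not tested. Fos stood at 0.47 there with the immediate early covariate, a list to which it belongs.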

Other observations

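Some lists that changed with age have not been described above. Myelin markers had 4 of 20 members higher with age in controls by both adjustments, with Apod at 0.54 and Myrf, the transcription factor of myelinating cells, at 0.31 (camera adjusted p = 0.0307, and adjusted p = 0.524 with an estimated correlation). That call was lost without control libraries 1, 3, 5 and 7 of 5 months (adjusted p = 0.102, 0.0872, 0.0712 and 0.0854) and control library 3 of 24 months (0.154). Neurotrophin and growth factor genes had 4 of 18 members lower by both adjustments, with Inhba, an activin subunit induced by activity, at -1.09 and Nptx2, a synaptic pentraxin, at -0.50 (camera adjusted p = 0.00834, and adjusted p = 0.311 with an estimated correlation). Oligodendrocyte precursor markers had 2 of 16 members lower with age in enriched mice by both adjustments, Gpr17 among them (camera adjusted p = 0.00295, and adjusted p = 0.0957 with an estimated correlation). Olfactory bulb markers had 1 of 9 lower with age in enriched mice, Sp8, which kept its call in 6 of 24 fits without a single library (adjusted p up to 0.146 in the others), and 7 adjusted over the list alone (camera adjusted p = 3.16e-05, and adjusted p = 0.154 with an estimated correlation), and fibroblast markers 2 of 13 lower and 3 adjusted over the list alone, with the collagen Col3a1 at -1.18 (camera adjusted p = 2.94e-04, and adjusted p = 0.484 with an estimated correlation). In controls the mean levels of these 2 lists lay the other way, at 0.31 for olfactory bulb markers (exact permutation p = 0.0956, adjusted p = 0.193) and 0.14 for fibroblast markers (p = 0.375, adjusted p = 0.541), and neither list was called. For fibroblast markers that direction rests on control libraries 4 and 6 of 5 months, at 3.32 and 3.36. The other 5 controls of that age had a mean of 3.97, and the 24-month controls ran from 3.78 to 4.08. Mean levels of p53 and senescence genes were 0.28 higher with age in enriched mice (exact permutation p = 0.00433, adjusted p = 0.0265).

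Arc levels varied widely within groups. They were 264 and 177 CPM in enriched libraries 1 and 2 of 5 months and 70.3 to 92.7 in the other 3, and 188 and 205 in enriched libraries 1 and 2 of 24 months and 58.3 to 67.1 in the other 4. In controls they were 372 to 384 in libraries 1, 2 and 3 of 5 months and 228 to 334 in the other 4, and 116 to 141 in libraries 4, 5 and 6 of 24 months and 60.1 to 64.9 in the other 3. The labels do not say whether sample numbers follow an order of collection, so handling that followed them was not tested, within groups or between them. Ly9, a surface receptor of lymphocytes named after its values were seen and below the expression limit of the naming rule, rose with age by 2.35 in controls (adjusted p = 2.73e-09) and by 1.95 in enriched mice (adjusted p = 1.55e-06). Without control libraries 4 and 6 of 5 months, the 41 genes called with enrichment at 5 months included 5 immediate early genes, with Egr3 at -0.41, Fosb at -0.73, Fosl2 at -0.55, Nr4a2 at -0.34 and Gadd45b at -0.62, and all 41 had the same sign with every library in the fit.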
